A study of Mus musculus with 248 samples.

How the data were processed

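Peripheral blood was taken repeatedly from mice with a conditional Cbfb-MYH11 knock-in (arm CM) and from littermate controls (arm Ctrl), and total RNA was sequenced in bulk. The training cohort held 132 libraries and the validation cohort 116 libraries, the former prepared with RiboErase. In the validation cohort the 38 libraries of T0, T1 and L were unstranded and the other 78 were stranded, so that fits across months 1 and 2 span a change of preparation in both arms. Every library came from a named mouse, and the replicates within a group are separate mice. Intervals are stated in months after induction (T0 to T10), in weeks (WK10 to WK28), or as leukemia (L) in the labels.

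The deposited values are reads per gene as CPM, the reads per 1e6 of the library, on a log2 scale (log2 CPM), with 1 table per cohort. Per the submitters' processing notes, reads were aligned with STAR to the mouse build GRCm38, counted with featureCounts of the Subread package and turned into log2 CPM with edgeR. Versions of these tools are not given in the sources used here. The names of the deposited tables state a filter for low genes of 0.5 CPM in 2 samples for the training and 5 CPM in 2 samples for the validation cohort. The values had been made with a prior of 0.25 reads scaled to the library size and without a composition factor. Turning them back gave whole reads for 100% of the values in every library, with a tolerance of 0.01 reads. Each library summed to 16 to 36.3 M reads in the training cohort and 8.68 to 34.4 M reads in the validation cohort. A gene with 0 reads therefore sat at a mean of -6.52 in the training table and at -6.3 in the validation table. A count of 0 was read as up to 3 reads per library, and such floors and intervals cover counting error only. There were 18508 genes in the training data and 13607 genes in the validation data, and 13232 were in both. Gene coordinates were taken from the RefSeq annotation of assembly GRCm38.p6.

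Groups, comparisons, tests, 20 gene lists, the rule for named genes and a first set of alternatives were fixed before the data were examined. Each arm comparison used the libraries of 1 month of 1 cohort, which is 1 library per mouse, with sex as a covariate. In the training cohort, the last library of each CM mouse was compared with its own T0 library, and Ctrl T1 and T10 with T0, with the mouse as a replicate block. The change from T0 to the last library in CM mice was compared with the change from T0 to T10 in Ctrl mice on the differences per mouse, with sex as a covariate. In the validation cohort, the L libraries were compared with T0 of the same mice, with the mouse as a replicate block. These 19 fits used limma 3.58.1 in R 4.3.3 with an intensity trend, moderated two-sided tests and Benjamini-Hochberg adjustment over all genes in the table. A call is a gene at an adjusted p under 0.05. All adjusted p values per gene in the text are from limma. Fold changes are given as log2 ± standard error, and group levels as mean log2 CPM ± SD.

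The gene lists were stem and progenitor, granule proteins of promyelocytes, mature neutrophil, monocyte, B cell, T cell, NK and cytotoxic, erythroid, platelet and megakaryocyte, basophil and mast cell, eosinophil, dendritic cell, interferon response, cell cycle, nucleolar and translation, immediate early, mitochondrial genome, inflammatory cytokines, transgene and partners, and sex chromosome check. Members were counted by the adjustment over all genes and, separately, adjusted over the list alone. Each list was tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 20 lists of a comparison.

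Named genes followed a rule. Where a comparison had at least 20 calls, it took the 10 largest increases and the 10 largest decreases with a mean log2 CPM above 1, the same direction in every CM mouse and a symbol that is not a predicted gene. It also took up to 4 called members of each list with the largest log2 fold change, and Kit, Cbfb and Myh11 in every comparison. A comparison with fewer calls took up to 10 genes in order of adjusted p. A comparison that repeats an earlier one was allowed to print fewer. Kit was chosen because the labels define leukemia by cKit-positive blasts.

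Principal components were computed by singular value decomposition of the gene-centred training values over all 132 libraries, with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The scores of the first 4 components in the 7 last CM libraries and the 7 Ctrl T10 libraries were compared by an exact permutation test over all 3432 splits, two-sided, with adjustment over the 4. The component with the largest absolute Spearman correlation with Kit was taken as the leukemia-related one. Kit was compared in the same libraries with the same test. Validation libraries were centred on the Ctrl mean of their own month and projected on the training loadings of the shared genes. Months 3 and 6 were planned for an exact test of the projection. Tests at the other months were added after the data were seen. Figures were drawn with matplotlib 3.10.9.

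The analysis was repeated, as laid down beforehand, with a filter on a mean log2 CPM above 1, log2(CPM + 1), quantile normalization, leaving out the sex covariate or the replicate block, each mouse left out in turn, 1 fit over all months with the mouse as a replicate block, the same fit with the library group of the titles, Ctrl T6 in place of T10, components of unit variance and an estimated correlation for the lists. Median-ratio scaling of the deposited log2 CPM, the removal of globin reads and voom on the recovered reads were chosen after seeing the data. So were Ctrl T5 in place of T10 and leaving out each mouse for the components and the projection. Tests of whether the arm difference changed between months or between sexes were also added after the data were seen. The WK libraries were left out of the comparisons, since they have at most 2 mice per arm at a week and follow another schedule.

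Each fit was tested on simulated reads that kept the real library sizes and the residual spread of each gene. The genes were drawn independently of each other, with the same spread in both arms. The false calls below therefore do not cover correlated genes or a larger spread in CM mice. Of the 18508 or 13607 genes 200 were changed, 100 by a log2 of 1 and 100 by a log2 of 2. In the training cohort, the larger changes recovered were 84 at month 0, 72 at month 1, 86 at month 2, 76 at month 3, 27 at month 4, 71 at month 5 and 4 at month 6, of 100 each. The smaller changes recovered were 60, 48, 49, 38, 0, 50 and 0 in the same order, with 8, 3, 8, 7, 0, 10 and 0 false calls. In the validation cohort, the larger changes recovered were 97, 96, 83, 84, 83, 89 and 84 at months 0 to 6, and the smaller ones 87, 79, 52, 56, 46, 66 and 41, with 8, 11, 8, 6, 12, 6 and 5 false calls. Of the larger and the smaller changes, 34 and 3 were recovered for the last CM library against T0 with 0 false calls, and 13 and 0 for its difference from controls with 0 false calls. The fit of Ctrl T1 against T0 recovered 79 and 56 with 8 false calls, that of Ctrl T10 against T0 recovered 33 and 0 with 2, and that of L against T0 recovered 72 and 47 with 7. A simulated component with 200 changed genes was recovered with an absolute correlation of 0.955 with its loadings and 0.999 with its scores. Counts called by voom on the recovered reads are given beside those of limma where they differ most or where limma called 0 genes.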

Results

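RNA of peripheral blood was sequenced repeatedly in mice of a leukemia model and in littermate controls. The CM mice carried a conditional Cbfb-MYH11 fusion allele, which is switched on in blood-forming cells by poly(I:C). All mice were given poly(I:C) at 14 mg/kg in 7 doses at 4 to 8 weeks of age, and leukemia was called in the labels at over 20% cKit-positive blasts. The training cohort held 7 CM mice with 55 libraries and 7 Ctrl mice with 77 libraries, sampled from month 0 (T0) to month 10. The last CM libraries were taken at months 4 to 10. The validation cohort held 13 CM mice with 68 libraries and 8 Ctrl mice with 48 libraries, sampled at months 0 to 6, at weeks 10 to 28 or in leukemia (L). Depth was 16 to 36.3 M reads per library in the training cohort and 8.68 to 34.4 M reads in the validation cohort. Each replicate is a separate mouse.

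The targeted gene Cbfb (ENSMUSG00000031885, chromosome 8, 105170674 to 105217989 on GRCm38.p6) codes for the partner of the RUNX factors, and Myh11 (ENSMUSG00000018830, chromosome 16, 14194527 to 14292188) for a smooth muscle myosin. The tables also list a transcript MHY11 without an Ensembl identifier. Its level in the validation cohort averaged 4.03 ± 0.44 log2 CPM (SD, 12 mice) in mice labelled CHW, the genotype of the CM arm, leaving out the mouse labelled CM with the number 2700. That mouse averaged -3.67 over 7 libraries. Controls labelled HW averaged 3.13 ± 0.06 (SD, 2 mice), those labelled CW -5.05 ± 0.97 (SD, 4 mice) and those labelled WT -5.14 ± 0.59 (SD, 2 mice). In the training cohort MHY11 averaged -2.81 ± 0.78 (SD, 7 mice) in CHW mice and -4.64 ± 0.45 (SD, 2 mice) in HW mice, and CW and WT mice had 0 reads. The genes of the sex chromosomes disagreed with the label in 1 of 248 libraries, the T0 library of CM mouse 2731 of the validation cohort (labelled F, Xist 1.24, Ddx3y 5.21). The later libraries of 2731 had Xist at 6.34 (T1), 2.08 (T2) and -1.18 (L) and Ddx3y at -2.35, -4.29 and -3.46, while Xist was at least 5.04 in all other libraries labelled F. Weaker mixed signals were also seen, with Xist up to 5.82 in male 2705 and 5.70 in male 2718 and Ddx3y up to 4.06 in female 2690. Mouse 2700 was kept in the CM arm, as labelled, in every validation comparison it entered.

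The arms were first compared before induction, at month 0. In the training cohort 1 gene was called, Pdgfra, a growth factor receptor gene, with 14 reads over the 7 CM libraries and 0 in the 7 Ctrl libraries, a depth at which no fold is given. Kit (ENSMUSG00000005672, chromosome 5, 75574987 to 75656722), the receptor that marks the blasts, stood at 1.98 ± 0.65 in CM and 1.75 ± 0.44 in Ctrl mice (SD, n = 7 each). Myh11 stood at 1.98 ± 0.18 in CM and -0.99 ± 1.87 in Ctrl mice, and did not pass (3.24 ± 0.66, adjusted p = 0.347). None of the 20 lists had a called member in either cohort at month 0, yet the preset list test called 4 lists in the training and 9 in the validation cohort before induction, and 0 with an estimated correlation. Among the validation mice limma called 0 genes with 10 CM and 6 Ctrl mice, with 208 genes at an unadjusted p under 0.05 and 0 by voom, and Kit stood at 1.36 ± 0.35 and 1.20 ± 0.52. The training table had 1715 genes at an unadjusted p under 0.05, and voom called 0.

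At month 1, red cell, platelet, mast cell and progenitor transcripts were higher in the blood of CM mice, and NK cell transcripts were lower. Large increases of the training cohort (7 CM and 7 Ctrl mice) included Ermap, a membrane protein of erythroblasts, at 4.66 ± 0.46, Rhd at 4.36 ± 0.59 and Rhag at 4.07 ± 0.52 of the Rh complex of red cells, and Kel, the Kell blood group protein, at 3.94 ± 0.54. Sox6, a factor of erythroid maturation, rose by 3.78 ± 0.46. Gstt1, a glutathione transferase, rose by 5.65 ± 0.76, the complement gene C4b by 4.76 ± 0.72, Pkhd1l1, a surface protein, by 4.66 ± 0.63, the keratin gene Krt5 by 4.57 ± 1.01 and the esterase Ces2g by 4.05 ± 0.57. Each was above the Ctrl mean in 7 of 7 CM mice, which the rule for named genes requires of the largest increases. Of 12 erythroid genes 11 rose and 0 fell (12 rose adjusted over the list alone), among them the factor Klf1, with 1083 reads against 14, and Slc4a1, the band 3 anion exchanger, by 3.46 ± 0.55. Of 13 platelet and megakaryocyte genes 11 rose and 0 fell (13 adjusted over the list alone), such as Gp1bb, a subunit of the von Willebrand receptor, by 1.70 ± 0.39. The reads of 4 globin genes moved with both lists, with a median of 2.65% in CM and 0.694% in Ctrl libraries.

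Progenitor and mast cell genes rose in the same month. Of 20 stem and progenitor genes 8 rose and 1 fell (10 and 1 adjusted over the list alone), with the factor Erg at 2.40 ± 0.43 and the surface antigen Cd34 at 2.32 ± 0.56. Kit rose by 1.87 ± 0.51 (adjusted p = 0.0456), from 2.12 ± 1.29 in Ctrl to 4.01 ± 0.57 in CM mice. The arms overlapped, since Ctrl mouse 3342 stood at 4.95, above the highest CM mouse at 4.62. The other Ctrl mice stood at 1.07 to 2.09. Of 9 basophil and mast cell genes 4 rose and 1 fell (5 and 1 adjusted over the list alone), including the carboxypeptidase Cpa3 by 3.16 ± 0.37 and Ms4a2, a subunit of the IgE receptor, by 2.36 ± 0.53. Of 20 cell cycle genes 9 rose and 0 fell (11 adjusted over the list alone), with cyclin A2, Ccna2, at 2.84 ± 0.41 and Mki67 at 2.29 ± 0.39. Rsad2 and Isg15, both known as interferon-induced, rose by 3.03 ± 0.49 and 2.39 ± 0.47, and 18 of 20 members of the interferon response list did not pass. Of 12 granule protein genes 1 rose (2 adjusted over the list alone).

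Genes of NK cells were lower at month 1. Of 12 NK and cytotoxic genes 6 fell and 0 rose (10 adjusted over the list alone), with the activating receptor Ncr1 at -1.64 ± 0.28, the receptor Klra8 at -1.67 ± 0.26 and granzyme A, Gzma, at -1.59 ± 0.33. The monocyte genes Cx3cr1, a chemokine receptor, at -1.39 ± 0.23 and Treml4 at -0.85 ± 0.19 were the 2 of 14 that fell (3 adjusted over the list alone). Large decreases included the lipid transporter Abca6 at -2.25 ± 0.29, the vesicle protein Cplx2 at -2.02 ± 0.35, the prostaglandin dehydrogenase Hpgd at -1.76 ± 0.30 and the scaffold protein Akap12 at -1.75 ± 0.28. Cbfb was lower at -0.61 ± 0.16. Myh11 differed by 4.13 ± 0.88, but its level followed the genotype of the controls, with 2.15 ± 0.25 in CM mice, 2.08 and 1.76 in the HW controls and at most -1.77 in the others. The immediate early gene Btg2, the cytokine gene Ccl4 and the dendritic cell gene Klk1 were the single members of their lists to fall. No member of the B cell, T cell, neutrophil, eosinophil, nucleolar, mitochondrial or sex chromosome lists passed. Under median-ratio scaling 7 of 15 T cell genes and 1 of 12 nucleolar genes rose, and under quantile normalization 5 and 1.

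In all, 929 genes were called at month 1 of the training cohort, 681 higher and 248 lower. The preset list test called the erythroid list, with adjusted p = 0.0821 with an estimated correlation, the stem and progenitor list, also with adjusted p = 0.0821 with an estimated correlation, and the platelet and cell cycle lists, each with adjusted p = 0.174 with an estimated correlation. The median fold change of all genes was -0.18 in the deposited scale and 0.02 under median-ratio scaling. Leaving out a Ctrl mouse gave 340 calls without 3350 and 412 without 3349, the 2 female controls, and leaving out a CM mouse gave 579 without 3368 and 612 without 3370. In 1 fit over all months with a replicate block the count was 409.

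**Figure D1:**
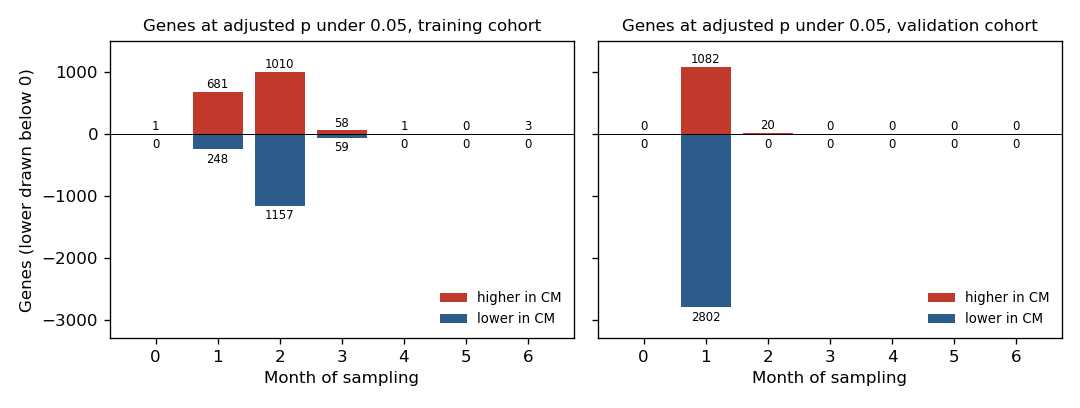
Bars give the number of genes called between arms (adjusted p under 0.05) at each month of sampling, with genes higher in CM above 0 and genes lower in CM drawn below 0. The counts were 929 and 2167 at months 1 and 2 of the training cohort and 3884 at month 1 of the validation cohort.

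At month 2 T cell genes were higher and B cell genes lower in CM mice of the training cohort, and progenitor, platelet and mast cell genes were among the increases. All 15 T cell genes rose and 0 fell (15 adjusted over the list alone), with the coreceptor Cd4 at 1.49 ± 0.21 and the costimulatory receptor Cd28 at 1.42 ± 0.25 (n = 7 mice per arm). Of 14 B cell genes 10 fell and 0 rose (13 adjusted over the list alone), with the factor Pax5 at -0.89 ± 0.17 and the inhibitory receptor Cd22 at -0.89 ± 0.18, and Vpreb3, a surrogate light chain protein, at -1.70 ± 0.15. The other large decreases were Cplx2 at -2.63 ± 0.34 and the chromatin reader Cecr2 at -2.02 ± 0.23. Gstt1 rose by 4.44 ± 0.59, C4b by 4.31 ± 0.44, Ermap by 3.36 ± 0.72, the actin-severing protein Scin by 2.92 ± 0.46 and Cpa3 by 2.83 ± 0.26. Kit rose by 2.05 ± 0.31 (adjusted p = 0.00139), and Cbfb, at -0.34 ± 0.10, did not pass (adjusted p = 0.0509).

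Of the stem and progenitor genes 7 rose and 1 fell at month 2 (8 and 1 adjusted over the list alone). Of the platelet genes 9 rose (13 adjusted over the list alone) and of the erythroid genes 3 rose (5 adjusted over the list alone). Of 14 mature neutrophil genes 4 rose and 0 fell (5 adjusted over the list alone), among them Camp, the cathelicidin of granules, by 2.31 ± 0.56 and the granule protein gene Ngp by 2.16 ± 0.44. Of 10 dendritic cell genes 1 rose and 3 fell (1 and 4 adjusted over the list alone), with the factor Irf8 at -0.76 ± 0.10. Of the monocyte genes 0 rose and 2 fell, and 1 rose and 1 fell under both other scalings. In the basophil and mast cell list 2 rose and 1 fell, in the NK and granule protein lists 1 rose and 1 fell, in the interferon list 2 rose and 1 fell, in the immediate early list 2 fell, in the cytokine list 1 fell and in the transgene and partner list 1 rose. The count of calls was 2167, 1010 higher and 1157 lower, and under median-ratio scaling 1430 higher and 1048 lower. The preset test called the T cell list, with adjusted p = 0.461 with an estimated correlation, the B cell list, with adjusted p = 0.488 with an estimated correlation, and the platelet list, with adjusted p = 0.479 with an estimated correlation. Without Ctrl mouse 3350 the count was 1261, and without Ctrl mouse 3346 it was 1422. In 1 fit over all months with a replicate block it fell to 161, and with the library group added to 93 higher and 14 lower.

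At month 3 the calls of the training cohort included higher Cpa3, Mcpt8 and Kit and 3 lower NK genes. Cpa3 rose by 5.27 ± 0.65, Mcpt8, a basophil protease, by 2.18 ± 0.38 and Kit by 2.47 ± 0.50 (adjusted p = 0.038, n = 7 mice per arm). C4b rose by 5.59 ± 0.44, Gstt1 by 2.99 ± 0.55, the cytokine receptor Il9r by 1.82 ± 0.28 and the mannose receptor Mrc1 by 1.76 ± 0.33. Mpo, the peroxidase of promyelocyte granules, rose by 2.08 ± 0.41. Sdc1, a syndecan of plasma cells, was lower at -2.22 ± 0.28, Akap12 at -2.14 ± 0.26, Vpreb3 at -1.79 ± 0.33 and Ncr1 at -1.75 ± 0.32. Of the basophil and mast cell genes 2 rose (6 adjusted over the list alone), of the stem and progenitor genes 1 rose and 1 fell (8 and 1 adjusted over the list alone), of the granule protein genes 1 rose (5 adjusted over the list alone) and of the NK genes 3 fell (6 adjusted over the list alone). Of the dendritic cell genes 2 fell (4 adjusted over the list alone), and 1 transgene and partner gene rose. No B cell gene passed over all genes, and 13 of 14 fell adjusted over the list alone. The basophil and mast cell list at month 3 was the single call of all list tests to hold with an estimated correlation (adjusted p = 0.0277 with an estimated correlation).

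The calls of month 3 were 58 higher and 59 lower, and under median-ratio scaling 91 higher and 46 lower. Leaving out a Ctrl mouse gave 17 calls without 3350, 22 without 3349, 57 without 3346, 58 without 3335 and 71 without 3339. Leaving out a CM mouse gave 41 without 3370, 52 without 3368 and 180 without 3341. The count was 356 without the sex covariate, 39 among genes with a mean log2 CPM above 1 and 188 in 1 fit over all months with a replicate block.

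At months 4 to 6 few genes were called in the training cohort, while Kit differed between single CM mice. At month 4 Igf1, insulin-like growth factor 1, was called, with 322 reads over 7 CM libraries and 4 reads over 7 Ctrl libraries. Of its CM reads 180 were in 1 library, and it did not pass without Ctrl mouse 3349 (adjusted p = 0.061) or 3350 (adjusted p = 0.0561). At month 6, with 5 CM and 7 Ctrl mice, 3 genes were called. Mcpt1, a mast cell protease, had 8153 reads in CM and 0 in Ctrl libraries and was at least 21.7-fold higher at the CM median. The chemokine gene Ccl24 had 296 reads against 2, and the signalling gene Wnt2 had 8144 reads against 1. A single CM library held 4785 of the reads of Mcpt1, 223 of those of Ccl24 and 5180 of those of Wnt2. With 1 of the 12 mice left out, Wnt2 passed without 3335, 3368 or 3370 and did not pass without any other mouse. Kit did not pass at month 4, at 3.77 ± 0.74 (adjusted p = 0.26), at month 5, at 1.64 ± 0.53 (adjusted p = 0.511), or at month 6, at 3.89 ± 0.86 (adjusted p = 0.161). Adjusted over the list alone, 18 of 20 cell cycle genes rose at month 6 and 11 at month 5, and 5, 7 and 5 stem and progenitor genes rose at months 4, 5 and 6.

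At month 5 limma called 0 genes, with 1583 at an unadjusted p under 0.05 and 0 by voom. The unadjusted counts were 1030 at month 4 and 1661 at month 6, where voom called 1 and 50. Without Ctrl mouse 3335 the month 5 count was 296, and at month 6 it was 26 without CM mouse 3370 and 11 without CM mouse 3368. These counts depend on the model. With a replicate block, 1 fit over all months called 355 genes at month 4 and 2490 at month 6. With the library group added it called 1624 at month 6. That fit shares 1 spread per gene over all months and both arms, while Kit in CM mice had an SD of 0.57 at month 1 and 2.73 at month 6. Whether this raised its late counts was not tested.

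In the validation cohort month 1 (10 CM and 6 Ctrl mice) again had higher red cell, mast cell and progenitor transcripts in CM mice. Mcpt1 had 27768 reads over 10 CM libraries and 10 over 6 Ctrl libraries. Col5a1, a collagen, rose by 5.34 ± 1.13, C4b by 4.52 ± 0.64, Gstt1 by 4.27 ± 0.84 and Il1rl1, the receptor for interleukin 33, by 3.89 ± 0.72. Kit rose by 2.15 ± 0.24 (adjusted p = 0.000727), from 1.14 ± 0.19 in Ctrl to 3.29 ± 0.58 in CM mice, and was above the Ctrl mean in 10 of 10. All 12 erythroid genes rose (12 adjusted over the list alone), with Klf1 at 3.08 ± 0.74 and Slc4a1 at 2.36 ± 0.44, and the median globin share was 4.47% in CM and 1.21% in Ctrl libraries. Of the stem and progenitor genes 10 rose and 1 fell, of the basophil and mast cell genes 5 rose and 1 fell and of 8 granule protein genes 3 rose, with the same counts adjusted over each list alone. Cpa3 rose by 3.37 ± 0.43, the lectin Fcnb by 3.72 ± 0.65 and Mpo by 2.51 ± 0.60. Of the cell cycle genes 10 rose (13 adjusted over the list alone), and of the platelet genes 9 rose (11 adjusted over the list alone).

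Genes of B cells and NK cells were lower at this month. Of 14 B cell genes 10 fell (13 adjusted over the list alone, and 4 under median-ratio scaling), with Pax5 at -0.96 ± 0.24 and the factor Ebf1 at -0.87 ± 0.21, and of 12 NK genes 9 fell (10 adjusted over the list alone), with Ncr1 at -1.20 ± 0.34. Large decreases included Klra4, an NK receptor, at -1.57 ± 0.45, the kinase Prkcc at -1.38 ± 0.34 and Rapgef3, an exchange factor that responds to cyclic AMP, at -1.36 ± 0.31. Of 19 interferon genes 5 rose, with Rsad2 at 2.34 ± 0.39, and 14 did not pass. Cbfb was lower at -0.34 ± 0.09 and Runx3 at -0.54 ± 0.14, as 2 of the 4 transgene and partner genes. Of the immediate early genes 3 fell, of the mitochondrial genes 1 of 6 fell, of 2 eosinophil genes 1 fell and of 9 dendritic cell genes 2 rose and 1 fell. Of 12 nucleolar genes 1 fell, while 1 rose under median-ratio scaling and 0 passed under quantile normalization. Of the neutrophil genes 1 rose and 1 fell, and no monocyte, T cell, cytokine or sex chromosome gene passed. The 3884 calls were 1082 higher and 2802 lower, by quantile normalization 1070 higher and 1759 lower, and by median-ratio scaling 1458 higher and 1018 lower. The preset test called the erythroid and stem lists, each with adjusted p = 0.13 with an estimated correlation, and the B cell list, with adjusted p = 0.513 with an estimated correlation. The count was 2060 without Ctrl mouse 2683, 2251 without Ctrl mouse 2689 and 2386 without Ctrl mouse 2692, and 4212 without CM mouse 2700. In 1 fit over all months with a replicate block it was 728.

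At month 2 of the validation cohort 20 genes were called, all higher in CM mice. Mcpt1 had 48017 reads against 17, the carbonic anhydrase Car1 rose by 6.47 ± 1.04, Col5a1 by 6.04 ± 0.99, the prostein gene Slc45a3 by 4.73 ± 0.80 and C4b by 4.21 ± 0.66. Kit did not pass, at 3.37 ± 0.72 (adjusted p = 0.115), and was above the Ctrl mean in 10 of 10 CM mice. Adjusted over the list alone, 19 cell cycle, 11 stem and progenitor and 5 erythroid genes rose and 6 NK genes fell. The 20 calls became 714 in 1 fit over all months with a replicate block, 4 among genes with a mean log2 CPM above 1, 0 with log2(CPM + 1), 1 by quantile normalization and 0 by voom, 2 without mouse 2683 or 2692, 3 without 2702 and 73 without 2700. They became 7 without 2720, 10 without 2684, 11 without 2689 or 2690 and 13 without 2719.

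At months 3 to 6 of the validation cohort limma and voom each called 0 genes, while 1 fit over all months with a replicate block called 2665 at month 3 and 5 at month 6. The genes at an unadjusted p under 0.05 were 2224, 369, 1169 and 469 at months 3, 4, 5 and 6. Kit stood at 4.01 ± 1.11 above Ctrl at month 3 (adjusted p = 0.298, 9 CM and 6 Ctrl mice), 2.28 ± 0.73 at month 4 (adjusted p = 0.772), 2.06 ± 0.64 at month 5 (adjusted p = 0.573) and 1.24 ± 0.55 at month 6 (adjusted p = 0.87, 4 CM and 6 Ctrl mice). Adjusted over the list alone, 9 cell cycle genes rose at month 3 and 15 T cell genes at month 5. CM mice left the cohort between months 3 and 6, and the mice that remained are not a random part of the group.

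**Figure D2:**
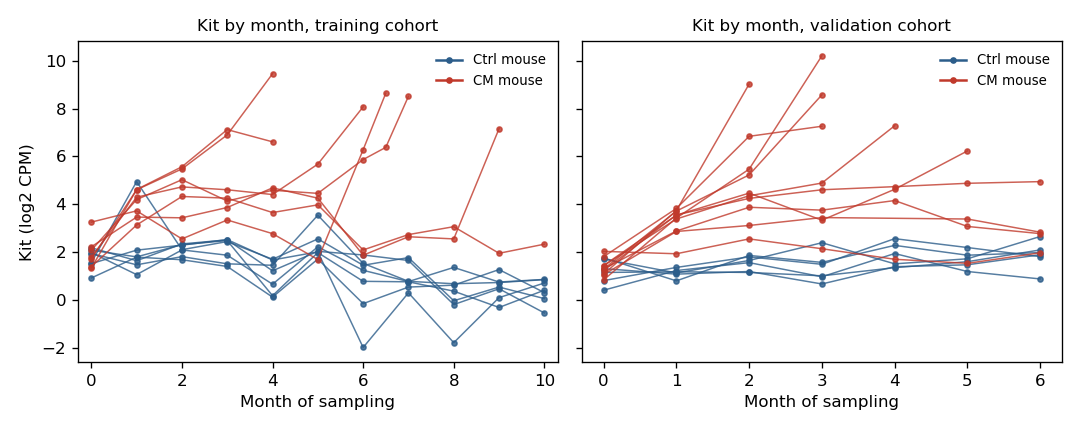
Lines follow the Kit level (log2 CPM) of each mouse by month of sampling, in the training and the validation cohort. In last samples of the training cohort CM mice reached 2.34 to 9.45, and Ctrl mice at month 10 stood between -0.53 and 0.87.

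The last library of each training CM mouse was compared with its own library before induction. Car1 rose by 10.25 ± 0.80, from 21 reads over the T0 libraries to 69004 over the last ones, Klf1 by 9.71 ± 1.04, from 18 to 29703 reads, and the sialomucin Podxl by 9.64 ± 1.10 (n = 7 pairs). Fcer1a, the alpha chain of the IgE receptor, rose by 9.28 ± 0.87, Slc45a3 by 8.78 ± 0.62, Ermap by 8.38 ± 0.75, Col5a1 by 8.18 ± 0.67 and Cpa3 by 8.16 ± 0.87, each in 7 of 7 mice. The rule for named genes requires that direction in every mouse of the largest increases. Kit rose by 5.28 ± 0.62. Of the stem and progenitor genes 13 rose and 2 fell (14 and 2 adjusted over the list alone), with Erg at 6.86 ± 0.83 and the factor Gata2 at 5.47 ± 0.40. Of the cell cycle genes 19 rose (19 adjusted over the list alone), with Ccna2 at 5.21 ± 0.33. Of the basophil and mast cell genes 5 rose and 2 fell, of the erythroid genes 6 rose, of the platelet genes 3 rose, of the granule protein genes 4 rose and 1 fell, and Myc was the 1 nucleolar gene that rose, by 1.58 ± 0.48. Cbfb, at 0.29, did not pass, and 1 of 5 transgene and partner genes rose.

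Genes of mature blood cells fell in the same pairs. All 14 B cell, 15 T cell and 12 NK genes fell, with Pax5 at -3.36 ± 0.34, Cd4 at -2.29 ± 0.29 and Ncr1 at -4.64 ± 0.37, and 11 of 14 monocyte genes fell. Of the mature neutrophil genes 7 fell and 0 rose, with the receptor Csf3r at -3.71 ± 0.49, and under quantile normalization 6 fell and 1 rose. Of the dendritic cell genes 9 of 10 fell, of the interferon genes 16 of 20 fell, with Mx2 at -4.44 ± 0.44, and of the immediate early genes 6 of 10 fell. Of the cytokine genes 8 of 12 fell, while 2 rose under both other scalings, and of 3 eosinophil genes 1 rose and 2 fell. The other large decreases included the protease Adamts14 at -4.94 ± 0.33, the heat shock gene Hspa1a at -4.59 ± 0.52 and the NK receptor gene Klri2 at -4.54 ± 0.38. Of 8508 calls 1869 were higher and 6639 lower, against 3628 and 5681 by median-ratio scaling and 3705 and 5082 by quantile normalization. The median fold change of all genes was -0.57, and -0.24 by median-ratio scaling. The preset test called the cell cycle list, with adjusted p = 0.432 with an estimated correlation, the stem list, with adjusted p = 0.315 with an estimated correlation, and the B cell list, with adjusted p = 0.455 with an estimated correlation.

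Control mice were compared with their own T0 libraries in the same way. From T0 to T1 limma called 0 genes (n = 7 pairs), with 1151 at an unadjusted p under 0.05 and 3 by voom. The genes in order of adjusted p began with Slx1b, a nuclease subunit, at -0.84 ± 0.08 and Adamts14 at -0.85 ± 0.08, both at an adjusted p = 0.055. Adjusted over the list alone, 10 of 12 NK genes fell, 5 basophil and mast cell genes rose and 2 immediate early genes fell. Kit stood at 0.37 ± 0.48 and Cbfb at -0.04 ± 0.07, and neither passed.

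From T0 to T10 red cell and platelet genes rose in controls and most genes of the white cell lists fell. All 12 erythroid genes rose, with Hba-a1 at 4.28 ± 0.49 and Alas2, the first enzyme of heme synthesis in red cells, at 4.27 ± 0.46, as did Hbb-b1, a beta globin, at 4.65 ± 0.57. All 13 platelet genes rose, with the chemokine Pf4 at 3.31 ± 0.34, and all 6 mitochondrial genes rose. All 14 B cell, 15 T cell and 12 NK genes fell, with the receptor Faim3 at -2.70 ± 0.44, the factor Lef1 at -2.91 ± 0.33 and Ncr1 at -3.73 ± 0.34. Of the neutrophil genes 11 fell and 1 rose, of the monocyte genes 12 fell and 1 rose and of the immediate early genes 10 fell, with Fosb at -4.88 ± 0.42. All 12 nucleolar genes fell, 16 interferon genes fell and 3 rose, 8 dendritic cell genes fell and 1 rose, 8 granule protein genes fell and 1 rose, and 1 eosinophil gene fell. Large increases included Tm4sf1, a membrane protein, at 5.54 ± 0.53 and Apol11b at 4.87 ± 0.45.

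The direction of some lists at T10 changed with the scaling. Of the stem and progenitor genes 4 rose and 8 fell, and 12 rose and 3 fell under median-ratio scaling. Of the cell cycle genes 8 rose and 8 fell, and 10 rose and 2 fell under median-ratio scaling, while of the basophil and mast cell genes 1 rose and 3 fell, and 2 rose and 0 fell under median-ratio scaling. Of the cytokine genes 4 fell, and 0 passed under median-ratio scaling, and of the transgene and partner genes 4 fell, and 2 rose and 1 fell under median-ratio scaling. No gene of the sex chromosome check passed, and 2 rose under median-ratio scaling. The 15389 calls were 1936 higher and 13453 lower, by quantile normalization 3852 and 7216, and by median-ratio scaling 5026 and 3265. The median fold change of all genes was -1.81 as deposited and -0.06 under median-ratio scaling. The median globin share went with it, from 1.02% at T0 to 31.2% at T10. Between these months the share did not rise steadily, with medians of 3.56% at T5, 29.9% at T6, 7.28% at T7 and 39.1% at T8.

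**Figure D3:**
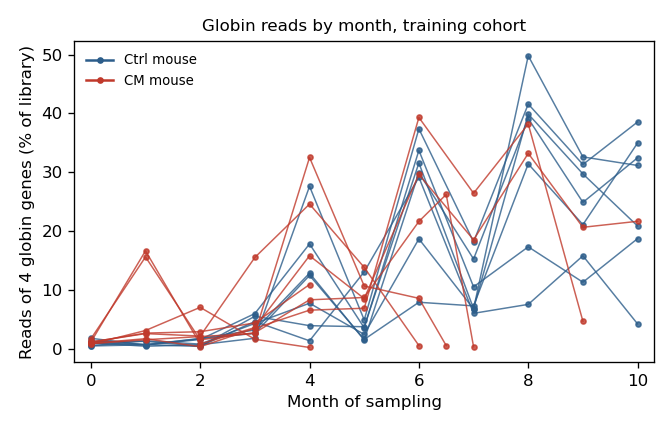
Lines follow the share of reads from 4 globin genes (percent of the library) of each training mouse by month of sampling. The Ctrl median was 1.02% at month 0, 0.694% at month 1, 12.5% at month 4 and 3.56% at month 5. It was 29.9% at month 6, 7.28% at month 7, 39.1% at month 8 and 31.2% at month 10, and so did not rise steadily.

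The change from T0 to the last library was then compared between the arms, which takes the control change into account (7 CM and 7 Ctrl mice). Nmnat2, an enzyme of NAD synthesis, rose by 8.20 ± 1.30 more in CM mice, Ms4a2 by 7.80 ± 1.09, Il1rl1 by 7.76 ± 0.97, the amino acid transporter Slc7a8 by 7.13 ± 1.02 and Kit by 6.32 ± 0.76. For Kit the mean change was 5.28 in CM and -1.36 in Ctrl mice, so its fall in controls is part of the difference. Erg rose by 7.84 ± 1.21 and Cpa3 by 7.57 ± 1.11 more. Of the stem and progenitor genes 12 rose and 1 fell relative to controls (14 and 2 adjusted over the list alone), of the granule protein genes 7 rose (9 adjusted over the list alone) and of the basophil and mast cell genes 6 rose (6 adjusted over the list alone). All 20 cell cycle genes rose relative to controls, with Cdk1 at 5.53 ± 0.89, and all 12 nucleolar genes did, with Myc at 3.52 ± 0.65. Nucleophosmin, Npm1, differed by 2.58 ± 0.59, which came from its level in controls, with a mean change of 0.46 in CM and -2.07 in Ctrl mice. Cbfb at 2.05 ± 0.52 and Runx1 at 2.11 ± 0.48 were among 4 of 5 transgene and partner genes that rose relative to controls. These differences came in large part from controls as well. The mean change in CM and Ctrl mice was 0.29 and -1.81 for Cbfb, 0.96 and -1.32 for Runx1 and -0.61 and -2.33 for Runx3.

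Most red cell and platelet genes called here rose less, or did not rise, against controls at T10. With Ctrl T5 in place of T10, Hbb-b1, Hba-a2 and Clec1b did not pass, as given below. Of the erythroid genes 7 fell and 3 rose relative to controls (8 and 3 adjusted over the list alone), with Hba-a2 at -3.43 ± 0.88, and Hbb-b1 stood at -4.15 ± 1.10. Of the platelet genes 7 fell (10 adjusted over the list alone), with the receptor Clec1b at -2.87 ± 0.80, and of 6 mitochondrial genes 5 fell. No B cell, T cell or monocyte gene passed, and under median-ratio scaling 11, 3 and 1 of them fell. Of the dendritic cell genes 1 fell. Of the interferon genes 2 rose and 3 fell, and 0 rose and 11 fell under median-ratio scaling, while of the immediate early genes 3 rose, and 1 rose and 1 fell under median-ratio scaling. Of the neutrophil genes 2 rose and 1 fell, and 0 rose and 1 fell under median-ratio scaling, and of the NK genes 1 rose and 1 fell, and 3 fell under median-ratio scaling.

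The 7151 calls of this comparison were 6240 higher and 911 lower, by quantile normalization 2763 and 2238, and by median-ratio scaling 2293 and 3439. The median fold change of all genes was 0.95 as deposited and -0.38 under median-ratio scaling. The preset test called the cell cycle, nucleolar and platelet lists, each with adjusted p = 0.544 with an estimated correlation. The CM libraries were from months 4 to 10 and all Ctrl libraries from month 10. With Ctrl T6 in place of T10, as laid down beforehand, all 15 named genes checked were called or not as before, with 0 reversed. The median globin share of controls was 29.9% at T6 and 3.56% at T5. With Ctrl T5 in place of T10, chosen after the data were seen, 1422 were higher and 4863 lower, with a median of -0.43. Kit at 4.40, Erg at 6.43 and Cdk1 at 4.98 still passed, and Npm1 at 0.74, Runx1 at 0.80, Cbfb at 0.34, Hbb-b1 at -1.21, Hba-a2 at -1.10 and Clec1b at -0.13 did not. The count was 2471 without Ctrl mouse 3349, 2975 without Ctrl mouse 3350 and 3819 without CM mouse 3334.

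In the validation cohort the L libraries of 6 CM mice were compared with their T0 libraries. Tph1, the enzyme that starts serotonin synthesis, had 341550 reads over the 6 L libraries and 1 read over the 6 T0 libraries. Car1 rose by 11.39 ± 0.53, Slc45a3 by 9.80 ± 0.30, Il1rl1 by 9.70 ± 0.16, Cpa3 by 9.44 ± 0.46, Fcer1a by 9.24 ± 0.22 and Kit by 8.84 ± 0.38, each in 6 of 6 mice. The rule for named genes requires that direction in every mouse of the largest increases. Of the stem and progenitor genes 16 rose and 2 fell, with Hoxa9 at 7.36 ± 0.80. Of the basophil and mast cell genes 6 rose and 1 fell. All 20 cell cycle genes rose, 8 of 12 nucleolar and 6 of 8 granule protein genes rose and 1 granule protein gene fell, and 5 of 6 mitochondrial genes rose. Runx1 at 2.49 ± 0.10 and Cbfb at 1.15 were among the 3 of 4 transgene and partner genes that rose.

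All 14 B cell and 15 T cell genes fell in leukemia, as did 11 of 12 NK genes, with Ncr1 at -6.60 ± 0.45, and 18 of 19 interferon genes. Of the platelet genes 10 fell and 1 rose, with Pf4 at -4.70 ± 0.32. Of the erythroid genes 6 fell and 3 rose, among the latter Klf1 at 7.42 ± 0.42, and the median globin share was 2.12% in CM mice at T0 and 0.12% in L libraries. Of the monocyte genes 9 fell, of the neutrophil genes 7 fell and 1 rose, of the dendritic cell genes 8 fell, of the eosinophil genes 2 of 2 fell, of the immediate early genes 8 fell and of the cytokine genes 9 fell and 1 rose. Gng11, a G protein subunit, was lower at -7.38 ± 0.24. Of 8772 calls 4278 were higher and 4494 lower, and 8459 genes were called without mouse 2731, whose T0 library did not match its sex label. The preset test called the B cell list, with adjusted p = 0.316 with an estimated correlation, and the cell cycle list, with adjusted p = 0.361 with an estimated correlation. The L libraries form a sequencing batch without controls by their labels, so this comparison alone does not separate batch from leukemia, though Car1, Slc45a3, Cpa3 and Kit also rose in the last libraries of the training cohort.

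**Figure D4:**
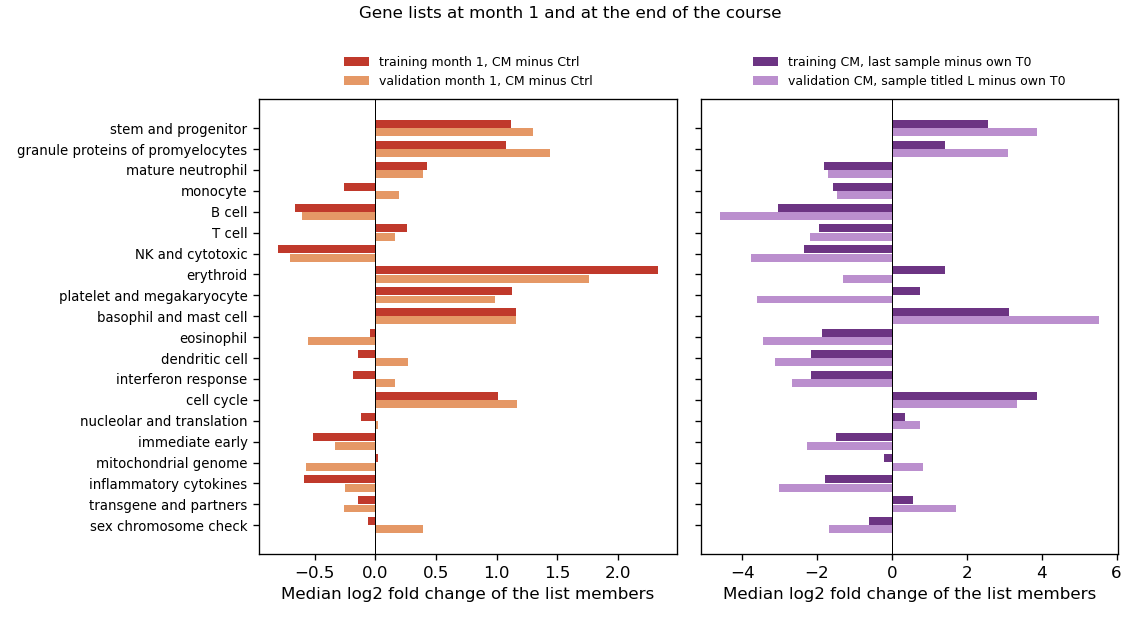
Bars give the median log2 fold change of the members of each of the 20 gene lists at month 1 (left) and at the end of the course (right). At month 1 the erythroid list has the largest median of the 20 lists in both cohorts, 2.33 and 1.76, and at the end the cell cycle list stands at 3.87 and 3.35 and the B cell list at -3.03 and -4.60.

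Of the 380 list tests over the 19 comparisons, 191 were called at the preset correlation and 1 with an estimated correlation. No sex chromosome gene was called in any of the 19 comparisons as deposited.

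Kit in the last libraries averaged 7.25 ± 2.36 in CM mice (SD, n = 7) and 0.39 ± 0.50 in Ctrl mice at T10 (SD, n = 7). The difference of 6.86 had an exact permutation p = 0.000583, the smallest the 3432 splits allow. At T10, 7 of 7 CM mice were above all controls, though the CM libraries were from months 4 to 10. Kit in controls averaged 1.75 at T0 and 0.39 at T10. The lowest CM value, 2.34 in mouse 3368, was below the highest control at T1 (4.95) and at T5 (3.55). The second principal component, which held 11.1% of the variance, was the one most related to Kit (Spearman rho 0.622 over all training libraries, which are repeated samples of 14 mice). It had positive loadings for 20 of 20 cell cycle, 12 of 12 nucleolar, 17 of 20 stem and progenitor and 11 of 12 granule protein genes and for 0 of 14 B cell and 0 of 15 T cell genes. Its score was 183.2 ± 94.3 in last CM libraries and -26.2 ± 8.7 in Ctrl T10 libraries (SD, n = 7 each), with an exact permutation p = 0.000583, adjusted p = 0.00233, and 7 of 7 CM mice above all controls. With a mean log2 CPM above 1 it was 6 of 7 (exact permutation test, adjusted p = 0.00466). The same libraries entered the decomposition and the choice of the component by Kit. The test of component 2 is therefore not independent of the Kit test. The last library of mouse 3368 scored -9.5, and the other 6 scored 153.8 to 255.3. The first component held 47% of the variance, with positive loadings for 14 of 14 B cell and 15 of 15 T cell genes and for 0 of 12 erythroid and 0 of 13 platelet genes. It differed by 134.4 (exact permutation p = 0.0286, adjusted p = 0.0571), and the adjusted p was 0.0245 with unit variance, 0.0221 with a mean log2 CPM above 1 and 0.049 with median-ratio scaling. For the other 2 components the exact permutation tests gave an adjusted p = 0.369 and an adjusted p = 0.848.

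**Figure D5:**
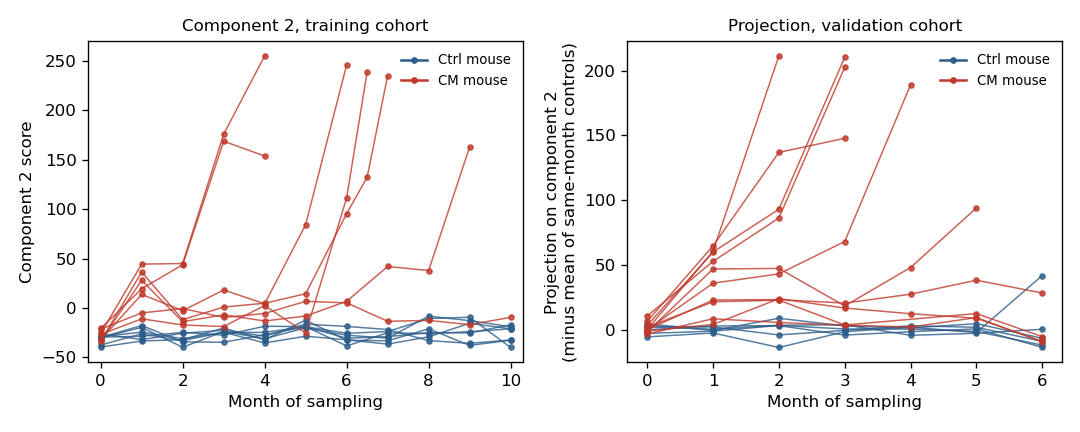
Lines follow each mouse by month of sampling, as its score on component 2 in the training cohort and as the projection on that component, minus the mean of same-month controls, in the validation cohort. The last CM libraries averaged 183.2 and the Ctrl T10 libraries -26.2.

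The training component was then applied to the other cohort. At month 3 the projection averaged 76.8 ± 86.5 in 9 CM mice and 0.0 ± 2.9 in 6 Ctrl mice (SD), with an exact permutation p = 0.0446 and an adjusted p = 0.0891 over the 2 planned months, and 7 of 9 CM mice were above all controls. At month 6 the difference was 1.0 (4 CM and 6 Ctrl mice, exact permutation p = 0.919), and it was -8.1 without CM mouse 2686 and 9.4 without Ctrl mouse 2702. The 6 L libraries, centred on the T0 controls, averaged 197.2 ± 12.5 (SD), against at most 4.4 in a control at T0. The T0 controls are of another batch and were centred on their own mean. This centring therefore does not remove a batch shift of the L libraries.

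Across the 13232 genes shared by the tables, the CM change relative to controls in the training cohort correlated with the change from T0 to L in the validation cohort (Pearson r 0.733, Spearman rho 0.715). The values for L, here and for each mouse below, do not separate batch from leukemia. Genes are not independent replicates, and no p is given over them. With the arm differences of the validation cohort, r and rho were 0.606 and 0.617 at month 3, 0.776 and 0.769 at month 4, 0.375 and 0.372 at month 5 and -0.185 and -0.197 at month 6. Computed for each mouse, r averaged 0.679 ± 0.034 (SD, 6 mice) for L, 0.267 ± 0.348 (SD, 9 mice) at month 3, 0.486 ± 0.175 (SD, 5 mice) at month 4, 0.217 ± 0.231 (SD, 5 mice) at month 5 and -0.119 ± 0.094 (SD, 4 mice) at month 6.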

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

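All tests of causes in this part, other than the one of the library group, were chosen after the results were seen. A rule that looks for a library apart from its group picks about 1 in 20 groups by chance, and 12 of 81 were picked against 4.0 awaited. Most of the 12 were MHY11 in mouse 2700 at different months, which are repeated samples of 1 mouse and not independent picks.

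Kit in 1 Ctrl mouse of the training cohort, 3342, stood at 4.95 log2 CPM at T1, and the other 6 Ctrl mice stood between 1.07 and 2.09. No test of its cause was run.

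MHY11, read here as the knock-in transcript because its level follows the genotype labels, was low in the mouse labelled CM with the number 2700 of the validation cohort at every month. It was at -1.17 at T0 (others 3.52 to 4.02), 0.05 at T1, -1.45 at T2, -6.3 at T3, -6.3 at T4, -4.24 at T5 and -6.3 at T6 (others at least 2.79 at every month). Kit in this mouse was 1.94 at T1, against 2.87 to 3.83 in the other 9 CM mice. A swap with a control labelled CW or WT is excluded, as the highest mean in such a mouse was -4.07 and the lowest in the other CM mice 3.30. A swap with an HW mouse is excluded, since Ddx3y was at least 6.44 in every library of those males and at most -0.70 in 2700. Too few reads is excluded, as 215 reads were awaited in its smallest library. The MHY11 level itself went against the genotype label CHW. Its mean was -3.67, near the -4.07 of the highest CW or WT mouse and far from the 3.30 of the lowest other CM mouse. The projection could not tell whether the arm label is wrong, since it was at or below the highest control in 3 of the months 1 to 5.

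Training controls at month 10 were lower than at month 0 in most genes, with a median of -1.81. Globin reads taking the place of others are excluded as the whole cause, since the median was -1.38 with them left out. Dilution of white cell RNA by red cell and platelet RNA stays open, as the medians of 5 white cell lists all fell and ranged over 0.87, between the median SD within a list of 0.65 and the largest of 1.95. The library group is excluded, because the difference within group G1 was -1.57. Age, repeated sampling and handling were not tested.

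The calls at month 1 of the validation cohort were mostly lower in CM mice. Whether scaling without a composition factor is the cause cannot be told, since 58.9% of the calls were higher under median-ratio scaling and 37.8% under quantile normalization. A single mouse is excluded, as at most 33.3% were higher with any mouse left out.

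Projections on the training component had 3 values apart from their group. CM mouse 2684 stood at 189.1 at T4 (others 1.9 to 47.9), CM mouse 2686 at 28.2 at T6 (others -9.6 to -5.5) and Ctrl mouse 2702 at 41.7 at T6 (others -13.8 to 0.2). No cause was tested.

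The arm difference changed from month 0 to month 1 in 222 genes of the training cohort and in 1704 genes of the validation cohort. For Kit this change was 1.62 ± 0.63 (adjusted p = 0.35) in the training cohort, where it did not pass, and 1.99 ± 0.37 (adjusted p = 0.00632) in the validation cohort. Across months 1 and 2 of the validation cohort the library preparation also changed, in both arms. From month 1 to month 2, and from month 1 to month 6, limma found 0 genes in either cohort, with 1005 and 2367 genes at an unadjusted p under 0.05 in the training cohort and 1353 and 160 in the validation cohort. Between the sexes the arm difference changed in 0 genes at months 1 and 2, with unadjusted counts of 688 and 1887 in the training cohort and 312 and 940 in the validation cohort. The change from T0 to the last library differed between the arms in 7151 genes.

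The libraries taken at weeks 10 to 28 entered no comparison, and they held high Kit levels in CM mice. Mouse 3200 went from 5.43 at WK10 to 6.44 at WK14 and 9.27 at WK18. Mouse 3130 went from 5.62 at WK20 to 8.95 at WK24 and 11.19 at WK25, and mouse 3131 from 3.35 at WK20 to 8.05 at WK24 and 9.70 at WK28. The 6 libraries of 2 Ctrl mice stood between 1.02 and 2.13, so that 9 of 9 libraries of 3 CM mice were above all of them. No test was made with 3 and 2 mice.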

How the results depend on the processing

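Median-ratio scaling, removal of globin reads, voom, the Ctrl T5 library and each mouse left out of the components and projection were chosen after the results were seen. The cause was not tested for any of the differences below.

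With a mean log2 CPM above 1, the training counts were 0 at month 0, 578 at month 1, 39 at month 3, 0 at month 4 and 0 at month 6, the validation count was 4 at month 2, the last library gave 4483, Ctrl T1 2 and Ctrl T10 10155, and the correlation at month 6 was -0.299. With log2(CPM + 1), the training counts were 0 at month 0, 0 at month 4, 1 at month 5 and 0 at month 6, the validation count was 0 at month 2 and Ctrl T1 gave 5. With quantile normalization they were 0 at month 0 and 44 at month 6 of the training cohort, 1 at month 2 of the validation cohort and 1 for Ctrl T1. Without the sex covariate they were 356 at month 3 and 1 at month 6 of the training cohort. With no replicate block Ctrl T1 gave 24. With an estimated correlation 1 list test was called in place of 191.

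With median-ratio scaling the training counts were 0 at month 0, 2 at month 4 and 5 at month 6, the validation count was 2476 at month 1 and Ctrl T10 gave 8291. With globin reads left out they were 7 at month 6 of the training cohort and 2 for Ctrl T1. By voom they were 0 at month 0 and 50 at month 6 of the training cohort, 0 at month 2 of the validation cohort and 3 for Ctrl T1.

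In 1 fit over all months with a replicate block, the training counts were 0, 409, 161, 188, 355 and 2490 at months 0, 1, 2, 3, 4 and 6, and the validation counts 728, 714, 2665 and 5 at months 1, 2, 3 and 6. That fit shares 1 spread per gene over all months and both arms. Its counts thus do not allow for a larger spread in late CM libraries. With the library group added, the training counts were 0, 370 and 1624 at months 0, 1 and 6. At months 2 and 4 this fit gave 93 higher and 14 lower, and 81 higher and 33 lower, each total 1.1e+02 when rounded.

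With each mouse left out in turn, the training counts ranged from 0 (without 3334, 3349 or 3350) to 1 at month 0, 340 (without 3350) to 1379 (without 3334) at month 1, 1261 to 2407 at month 2, 17 (without 3350) to 180 (without 3341) at month 3, 0 (without 3349 or 3350) to 3 (without 3338) at month 4, 0 to 296 (without 3335) at month 5 and 2 to 26 (without 3370) at month 6. The validation counts ranged from 2060 (without 2683) to 4979 at month 1, 2 (without 2683 or 2692) to 73 (without 2700) at month 2 and 0 to 5 (without 2685) at month 5, and were 0 throughout at months 0, 3, 4 and 6. The last library gave 7198 to 10824, its change against controls 2471 (without 3349) to 9603, Ctrl T1 0 to 1 (without 3335), Ctrl T10 14576 to 15680 and L 7667 to 8550. The projection at month 3 was 60.1 to 86, and passed without 2700 (86) and without 2709 (85.9), each with an adjusted p = 0.046 by the exact test. At month 6 it was -8.1 (without 2686) to 9.4 (without 2702). Kit in last libraries differed by 6.5 to 7.68.

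The depth limits what can be said of genes such as Pdgfra, Igf1 and Ccl24, which had few reads in one arm.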

Other observations

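The comparison of the cohorts at month 1, the projections outside months 3 and 6 and the split of month 1 across cohorts were chosen after the results were seen. Genes called at month 1 were shared between the cohorts more often than independent lists would share. Of the 13232 shared genes 576 were higher in the training and 1074 in the validation cohort, and 485 in both, where independent lists would share 46.8. Lower were 186 in the training and 2709 in the validation cohort, and 148 in both, where independent lists would share 38.1, and 0 genes had opposite calls. The decreases of the validation cohort depend on the scaling, with 1018 of all its genes lower under median-ratio scaling. The fold changes correlated (Pearson r 0.84, Spearman rho 0.669), though genes are not independent replicates. Of 100 splits of the training mice, the real one was the only 1 to reach this correlation. The highest other was 0.828, close to the real value. A false arm thus gave nearly the same correlation, and chance is not taken as excluded.

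The projection on component 2 was already higher in CM mice of the validation cohort at month 1. It averaged 37.7 ± 22.5 in 10 CM mice (SD), with an exact permutation p = 0.00212 and an adjusted p = 0.00758 over 7 months, and 10 of 10 CM mice were above all 6 controls. At month 2 the difference was 69.3 (adjusted p = 0.021, exact permutation test, 9 of 10 above), at month 4 55.7 (adjusted p = 0.0101, exact permutation test, 4 of 5 above, with mouse 2684 at 189.1 and the other CM mice at 1.9 to 47.9) and at month 5 32.5 (adjusted p = 0.00758, exact permutation test, 5 of 5 above). It did not pass at month 0, with a difference of 1.5 (exact permutation p = 0.495), at month 3, with 76.8 (adjusted p = 0.0624 over 7 months, exact permutation test, 7 of 9 above), or at month 6, with 1.0 (adjusted p = 0.919, exact permutation test).

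Mice were split into false arms to see what chance gives. The mark set for excluding chance was a share under 0.05 of splits that reach the real count, not adjusted over the 19 comparisons. This mark is not taken as enough where a false arm called more genes than the real one, or came close to it. Nor is it enough where the real count fell below a false arm with 1 mouse left out. Where the real count was 0, every split reaches it, so the splits decide nothing there. In the training cohort the real count was reached in 4 of 100 splits at month 0 (1 real, highest other 5), in 1 of 100 at month 1 (929, highest other 876), in 1 of 100 at month 2 (2167, highest other 232), in 1 of 100 at month 3 (58 higher and 59 lower, highest other 69), in 3 of 100 at month 4 (1, highest other 2882) and in 3 of 100 at month 6 (3, highest other 5810), the real split being among them. No other split drawn reached the real count at months 1, 2 and 3. At month 2 the highest other was far below it, so chance can be excluded there by that share. At month 1 a false arm came close, with 876. Without mouse 3350 the real count was 340 at month 1 and 17 at month 3, below the highest false arm. Chance is therefore not taken as excluded at months 1 and 3. At months 0, 4 and 6 the median count of the other splits was 0, so even 1 or 3 calls give a share under 0.05. Some false arms called several times the real count there. The splits therefore do not exclude chance at months 0, 4 and 6, and the calls of 1 and 3 genes are given no weight. Why some false arms called so many genes was not tested. At month 5 the real 0 was reached in 100 of 100 (highest other 625). In the validation cohort the real count was reached in 1 of 100 splits at month 1 (3884, highest other 0), so chance can be excluded there. At month 2 it was reached in 2 of 100 (20, highest other 593). A false arm thus called more genes than the real one, so the splits do not exclude chance at month 2. At months 0, 3, 4, 5 and 6 the real 0 was reached in 100 of 100 splits, with highest others of 0, 50, 488, 2294 and 2.

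For pairs, the last CM library against T0 was alone in 64 splits (8508, highest other 3119), as was the Ctrl T10 library against T0 (15389, highest other 13876), and the L library was alone in 32 splits (8772, highest other 0). That is, 1 of 64, 1 of 64 and 1 of 32. Chance can be excluded by the same unadjusted share for the last CM library and for L. For Ctrl T10 a false split came close, so chance is not taken as excluded there. For Ctrl T1 against T0 the real 0 was reached in 64 of 64 (highest other 0), which decides nothing. The change from T0 compared between arms was reached in 3 of 100 splits (7151, highest other 9447). This share is under 0.05, but a false arm called more genes than the real one, so the count does not exclude chance. Why it did was not tested.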
